A study of Mus musculus with 2 samples.

How the data were processed

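Single-cell RNA of intratumoral immune cells was measured with droplet libraries from 2 groups of female mice carrying B16Ova melanoma in the flank. The wildtype (WT) animals lacked the E8i-cre transgene and carried floxed Tcf7 alleles, and the knockout (KO) animals carried the same alleles with E8i-cre. E8i-cre is active in mature CD8 T cells. Per the labels, tumors were taken on day 13, 3 tumors per group, and 2000 cells of each of 4 sorted categories were taken per tumor. The categories were CD8 T cells, CD4 T cells, a dendritic cell gate, and other CD45-positive cells, and 7000 cells were loaded per channel. The deposited values give 1 library per group, and the barcodes do not say which tumor a cell came from.

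The deposited matrices hold raw UMI counts, per the file headers and per the values, which are whole numbers. The submitters' processing notes name Cell Ranger version 1.3 and the mm10 build, while the matrix header names software version 3.0.2. Both are given here because the files do not settle which release made the counts. The annotation release is not given in the sources used here, nor are the exons removed by the Cre or whether the chemistry reads the 3' or the 5' end. Each matrix has 27998 genes, of which 121 symbols occur more than once. For positions, gene IDs were matched to the GENCODE mouse annotation on GRCm38, which is the same assembly as mm10, and 27645 of the 27998 IDs (98.7%) were found.

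Cells were kept with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs. This left out 132 of 1120 WT barcodes and 133 of 1219 KO barcodes. Scrublet, as run in scanpy with an expected doublet rate of 6%, called 6 WT and 5 KO barcodes above its thresholds of 0.302 and 0.304, and these were left out. Those calls are 0.607% and 0.460% of the filtered barcodes, below the 6% given to Scrublet. That 6% was a setting and not a rate measured here, so the calls do not tell how many doublets remain. A cluster of 20 WT and 10 KO cells with markers of T cells and of type 1 conventional dendritic cells (cDC1s) in the same cells was left unnamed for that reason. A cluster of 27 WT and 22 KO cells with median depths of 794 and 998 UMIs was also left unnamed. Its 10 leading genes held Il7r, of the naive set, but none of the T cell, CD8 or CD4 sets, and other clusters without such a gene were named because they were deeper.

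Both libraries were clustered together on log-normalised counts scaled to 10000 per cell, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1, which gave 19 clusters. Tcf7, antigen receptor segment genes and mitochondrial genes were kept out of the variable genes. Clusters were named from marker sets, with at least 3 markers detected in at least 25% of cells. Some markers of the sets were not used here. CD8 T cells were cells of T cell clusters with a UMI of Cd8a or Cd8b1 and none of Cd4, and CD4 T cells the reverse. Cells with neither or both are given by number. Cycling was treated as a state and not as a class.

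For each class, counts were summed per library and scaled by the class total to CPM, with an exact Poisson 95% interval. The ratio of KO to WT CPM has an exact conditional binomial 95% interval. Shares of cells have Clopper-Pearson 95% intervals, and differences of shares have intervals that join those bounds. Where a count was 0, the floor was 3 counts over the library's class, and for shares 3 cells. These intervals cover counting error only. With 1 library per group there are no replicates, the animals of a group cannot be separated, and no test of WT against KO was possible, so no p-value was computed. A gene or list is therefore described as higher or lower by its values in these libraries.

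Gene lists were described by the median log2 ratio of the members with at least 50 CPM in 1 library, in classes with at least 50 cells in both libraries. A member counted as higher or lower when its ratio was at least 1.5-fold with an interval that excludes 1. The median has an interval from 400 Poisson draws of the counts. Its percentile is its place among 10000 random lists of the same size, drawn within 20 expression bins. Genes are not independent replicates, so the percentile describes the list and is not a test. The numbers of genes measured were 2621 in CD8 T cells, 2926 in CD4 T cells, 2432 in cDC1s, 2446 in mature dendritic cells (DCs) and 2811 in macrophages.

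Named genes followed a rule. In CD8 T cells these were 12 fixed genes, of which 11 are reported, the 10 highest and the 10 lowest genes, ranked by the interval bound nearest to 1. CD4 T cells had Tcf7, Cxcr6 and the 5 highest and 5 lowest, and other classes had Cxcl16, Cd80, Cd86 and the 3 highest and 3 lowest. For each list, 2 to 4 members with the largest ratio by the same bound were added. Antigen receptor, ribosomal, mitochondrial, haemoglobin and gating genes were left out of the ranking, as were markers of other cell types in T cells. Any other gene is said in the text to have been chosen after its values were seen.

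Because KO cells were deeper, shares of cells with a UMI were computed after each cell was thinned at random to 2000 UMIs. This left out 9 WT and 4 KO CD8 T cells that were shallower, and unthinned shares are given too. Free RNA in droplets was read from the share in a class that should lack the gene.

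The grouping, classes, lists, named-gene rule and the first set of alternatives were fixed before the data were examined. These alternatives were doublets kept, a minimum of 1000 UMIs, no added cell filter, Leiden resolution 2, TMM scaling, CPM without ribosomal, mitochondrial and antigen receptor genes, the mean of each cell's CPM, gene minimums of 10 and 200 CPM, classes by cluster, gates that ignore the other co-receptor, no cells with a UMI of Mki67 or Top2a, and thinning to 4000 UMIs or not at all. Alternatives added after seeing the data left out the naive-like cluster, used it alone, left out T cells with over 0.5% of UMIs from antigen-presenting cell genes, left out each gene's top cell per library, and replaced the single thinning draw by the mean over all draws. Classes by cluster gave each whole T cell cluster to the co-receptor found in more of its cells. Only clusters 2 and 6 then counted as CD4. The CD4 T cells of naive-like cluster 1 (20 WT and 34 KO) and cycling cluster 5 (15 and 23) counted as CD8. Every list with at least 3 measured members was recomputed in each class. Single members of the metabolic, ribosomal, mitochondrial, MHC class I and Th1 lists, and of the inhibitory receptor and antigen-presenting cell lists in CD4 T cells, were not recomputed, a choice made after the tables were seen.

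The intervals were tested on simulated data of 462 cells with 200 changed genes. The ratio intervals held the true value for 95.2% of 2660 genes, and a 12-gene list set to 0.5 of its level came out at -1.08. Differences of thinned shares held 0 for 96.1% of 953 unchanged genes, but unthinned ones for 72.3%, so unthinned differences between the libraries follow depth in part. The simulated counts were Poisson draws, which vary less between cells than real counts do. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.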

Results

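The data were 2 droplet libraries of immune cells sorted from B16Ova tumors, B16 melanoma cells that carry ovalbumin. One library came from WT mice and the other from mice in which E8i-cre targets floxed Tcf7 in CD8 T cells. Tcf7 encodes TCF1, a transcription factor of naive and memory T cells. Each library pooled 3 tumors. The WT library held 1120 barcodes and 9283014 UMIs, with 504 to 48526 UMIs per barcode and a median of 5127. The KO library held 1219 barcodes and 11758449 UMIs, with 505 to 75823 per barcode and a median of 6820. After filtering, 982 WT and 1081 KO cells remained, with median depths of 6144.5 and 8112 UMIs. There were no replicates, so the values below describe these 2 libraries, and intervals cover counting error only.

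Monocytes and type 2 conventional DCs (cDC2s) made up more of the KO library, and mature DCs more of the WT library. Monocytes were 30 of 982 WT cells (3.05%) and 94 of 1081 KO cells (8.70%), a difference of 5.64 percentage points (3.58 to 7.73). The cDC2 share was 4.58% in WT and 8.97% in KO, and mature DCs, which express Fscn1 and Ccl22, were 9.88% and 5.46%. CD8 T cells (168 and 181 cells; 17.1% and 16.7%), CD4 T cells (170 and 171 cells; 17.3% and 15.8%) and cDC1s (175 and 186 cells; 17.8% and 17.2%) took like shares. The equal mixing of the sorted categories sets these shares in part, so a share compares only with others of its sorted category. The remaining cells were 63 and 57 macrophages, 17 and 28 NK cells, 18 and 12 plasmacytoid DCs, 7 and 9 B cells, 20 and 13 melanoma cells, 103 and 122 T cells with neither co-receptor, 22 and 20 with both, and 47 and 32 in unnamed clusters. A Cd4 UMI was present in 22 of 190 WT (11.6%) and 20 of 201 KO (9.95%) T cells with a UMI of Cd8a or Cd8b1, and those cells were left out of the CD8 class.

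**Figure D1:**
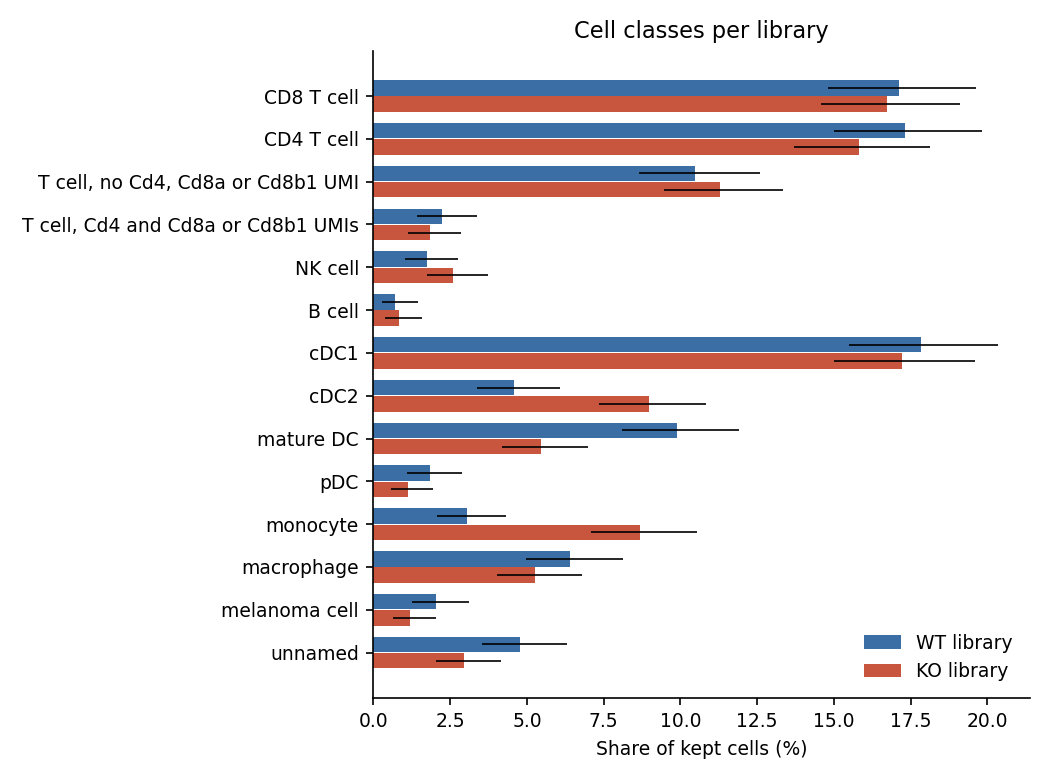
Share of kept cells in each class (percent of 982 WT and 1081 KO cells), with Clopper-Pearson 95% intervals as bars. Monocytes stood at 3.05% in WT and 8.70% in KO, and mature DCs at 9.88% and 5.46%.

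The comparison of CD8 T cells addresses the axis of TCF1, CXCR6 and CD28 named in the series title. KO CD8 T cells had lower Tcf7 and lower transcripts of naive and memory genes such as Slamf6, S1pr1 and Klf2, with higher transcripts of Gzmb, Prf1, Ccl4 and Ifng, which encode cytotoxic granule proteins, a chemokine and interferon gamma. Cxcr6, the receptor for CXCL16, was higher by 1.24 to 1.56-fold and was found in more cells. Cd28, the co-stimulatory receptor of CD80 and CD86, was at like levels, 124.8 CPM in WT and 119.3 in KO (ratio 0.778 to 1.18). Cycling genes were also higher. The median depths of the cells were 4787.5 UMIs in WT and 6926 in KO. Most WT CD8 T cells came from cluster 9 (69 cells, led by Gzmk and Gzma) and naive-like cluster 1 (43 cells). KO cells were spread over cycling cluster 5 (49), naive-like cluster 1 (45), cluster 11 (39, led by Prf1, Klrc1 and Cxcr6) and cluster 9 (36). Cluster 5 held 21 WT CD8 T cells. Over all its cells it was deep (medians of 20644 UMIs in WT and 20936 in KO), and cluster 1 was shallow (3818 and 3490.5). Summed counts weigh cells by depth, so a ratio for the CD8 class also holds this difference in make-up.

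Tcf7 in CD8 T cells stood at 152.5 CPM in WT (187 UMIs, 131 to 176) and 51.5 in KO (104 UMIs, 42.1 to 62.4), a log2 ratio of -1.57 (ratio 0.263 to 0.431). The gene lies at chromosome 11, 52252371 to 52283014, minus strand, on mm10. The labels do not give the deleted exons, and tags outside the deleted part check nothing about the deletion. Naive-like CD8 T cells held Tcf7 at 391 CPM in WT and 320 in KO (ratio 0.572 to 1.16), and the other CD8 T cells at 106 and 25.0 (ratio 0.163 to 0.336). These subsets were chosen after the data were seen. CD4 T cells, where the Cre is not described as active, had 126.7 and 79.8 CPM (ratio 0.483 to 0.819), with 452 and 430 in naive-like CD4 T cells and 103 and 44.7 in the others (0.305 to 0.609). T cells with neither co-receptor had 165 and 186 CPM, and NK cells 158 and 116. In cDC1s Tcf7 stood at 3.22 and 3.20 CPM, in cDC2s at 8.28 and 11.7, in mature DCs at 44.9 and 36.0, in plasmacytoid DCs at 46.4 and 12.9, in monocytes at 11.1 and 27.0, and in macrophages at 5.58 and 3.69. The log2 ratio in CD8 T cells moved to -0.79 with the mean of each cell's CPM, which weighs cells alike whatever their depth. It moved to -0.88 with classes by cluster.

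Cxcr6 in CD8 T cells stood at 352 CPM in WT (432 UMIs, 320 to 387) and 490 in KO (990 UMIs, 460 to 522), a log2 ratio of 0.48. It lies at chromosome 9, 123806475 to 123811760, plus strand. With cycling cells left out, that ratio was 1.14. Within cluster 9, Cxcr6 was 335 CPM in WT and 711 in KO (ratio 1.61 to 2.79), while cycling cluster 5 had 361 and 379 and cluster 11 had 698 and 793. In naive-like CD8 T cells it was 35.1 CPM (7 UMIs) in WT and 220.5 (40 UMIs) in KO, a ratio of 2.78 to 16.6. Cxcr6 was among the genes used for the clustering, so its levels within clusters were set in part beforehand. In CD4 T cells Cxcr6 was 173 and 143 CPM (ratio 0.669 to 1.02). A gene of the axis in the same cells, Cd28 (chromosome 1, 60716800 to 60773359, plus strand), was 237 CPM in WT and 178 in KO in CD4 T cells (ratio 0.624 to 0.898), but its log2 ratio turned to 0.079 with classes by cluster.

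**Figure D2:**
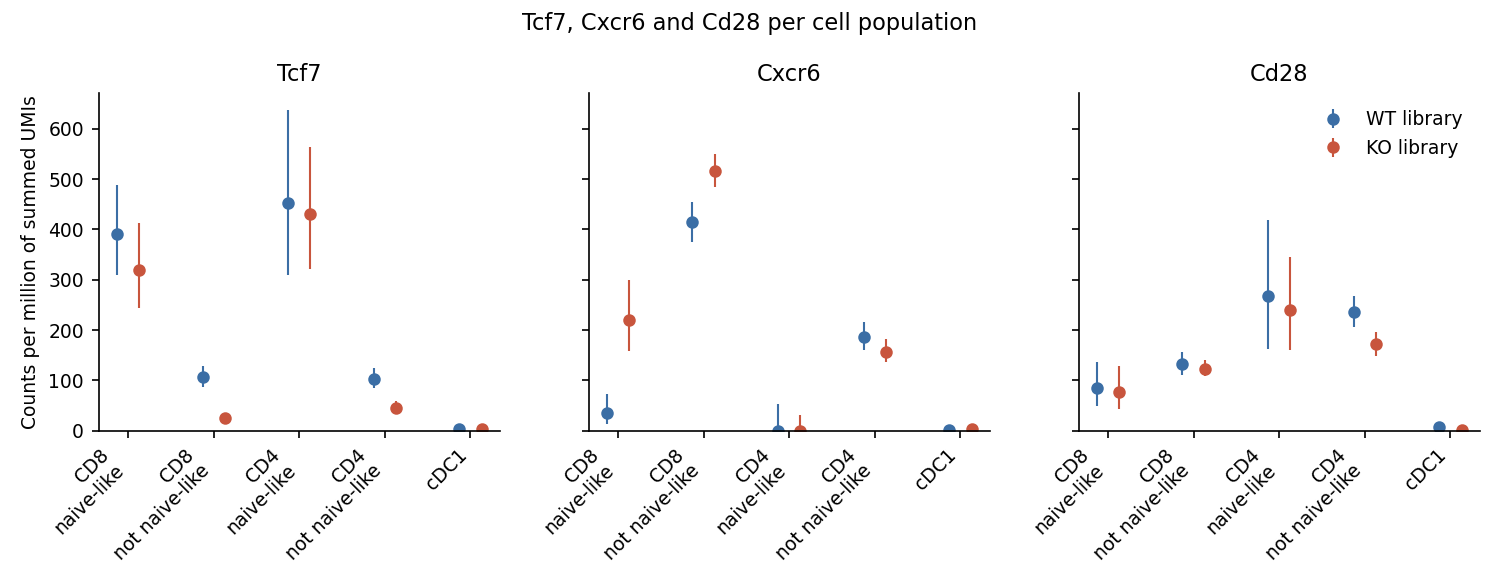
CPM of Tcf7, Cxcr6 and Cd28 in naive-like and other CD8 and CD4 T cells and in cDC1s of the WT and KO libraries, with exact Poisson 95% intervals as bars. Tcf7 in CD8 T cells outside the naive-like cluster stood at 106 CPM in WT and 25.0 in KO, and Cxcr6 at 414 and 517.

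At 2000 UMIs per cell, 45 of 159 WT CD8 T cells (28.3%, 21.5 to 36.0) and 98 of 177 KO cells (55.4%, 47.7 to 62.8) had a Cxcr6 UMI, a difference of 27.1 points (16.2 to 37.2). Without thinning the shares were 51.2% and 82.9%. In cDC1s, taken as cells without Cxcr6, 0 of 173 WT and 0 of 186 KO cells had a UMI after thinning, which allows up to 1.73% and 1.61%, and 1 of 175 and 1 of 186 had one unthinned. Their median depths were 16016 and 16746 UMIs. The Tcf7 share was 32.1% in WT and 20.9% in KO (difference -11.2 points, -20.9 to -1.33), and unthinned 51.8% and 31.5%, against 7 of 175 and 5 of 186 cDC1s. Gzmb, the protease granzyme B, was found in 28.9% and 53.1% of thinned CD8 T cells (difference 24.2 points, 13.3 to 34.4), with a UMI in 2 of 175 and 1 of 186 cDC1s unthinned. Pdcd1, which encodes the inhibitory receptor PD-1, was found in 26.4% and 39.5% (13.1 points, 2.65 to 23.3), Mki67 in 4.40% and 11.3% (6.90 points, 0.731 to 13.1; -0.257 in another draw without the 3 cells over 0.5% antigen-presenting cell UMIs), and Slamf6, a surface receptor kept on stem-like CD8 T cells, in 16.4% and 4.52%. Il7r, the receptor of the survival cytokine IL-7, was found in 39.0% and 29.9%, Lef1 in 23.3% and 20.3%, Tox in 17.6% and 26.6%, Lag3 in 17.6% and 23.2%, Havcr2 in 8.18% and 10.7%, and Ifng in 10.7% and 18.1%. The shares for Gzmk were 20.8% and 22.6%, for Cd28 22.0% and 21.5%, for Klrg1 3.77% and 3.39%, and for Cx3cr1 3.14% and 6.78%. Ccr7 (17.6% and 20.3%), a homing receptor of naive cells, ran against its CPM, so no order is read for it. Each thinned share is 1 random draw, whose own chance the intervals do not hold. Averaged over all draws, an alternative chosen after the data were seen, the Cxcr6 shares were 33.9% and 57.6%, a difference of 23.7 points with an SD over draws of 3.66. The same averages were 33.2% and 19.99% for Tcf7, 29.3% and 53.9% for Gzmb, 27.3% and 39.3% for Pdcd1, 4.79% and 9.79% for Mki67, 24.0% and 19.4% for Gzmk, 5.96% and 12.2% for Havcr2, and 15.6% and 6.89% for Slamf6.

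**Figure D3:**
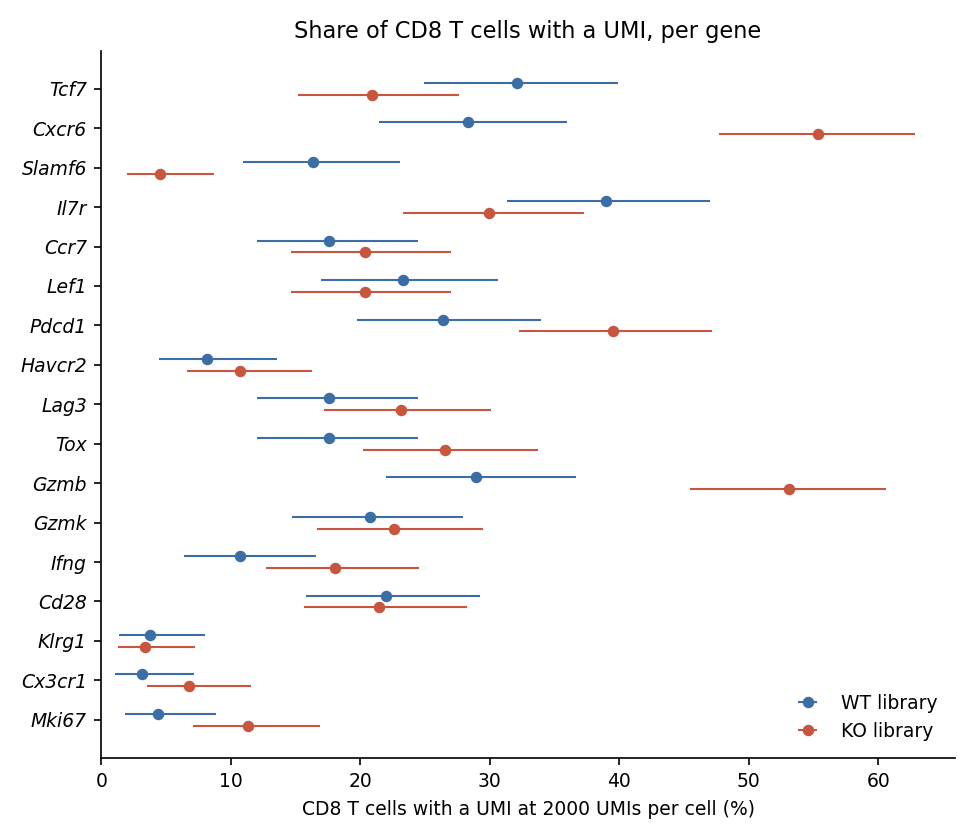
Share of CD8 T cells with at least 1 UMI of each gene after thinning to 2000 UMIs (percent of 159 WT and 177 KO cells), with Clopper-Pearson 95% intervals as bars. Cxcr6 stood at 28.3% in WT and 55.4% in KO, and Slamf6 at 16.4% and 4.52%.

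Within the WT library, 9 of 51 thinned CD8 T cells with a Tcf7 UMI (17.6%) and 36 of 108 without one (33.3%) had a Cxcr6 UMI, a difference of 15.7 points whose interval (-0.188 to 29.1) held 0. In the KO library the shares were 43.2% and 58.6%, a difference of 15.3 points (-3.97 to 33.5), and outside the naive-like cluster -7.25 points (-30.8 to 24.6). Among WT cells outside the naive-like cluster the shares were 40.0% with Tcf7 and 34.1% without, a difference of -5.85 points (-26.4 to 13.8). Without thinning, 42.5% of WT cells with a Tcf7 UMI and 60.5% of those without one had Cxcr6, a difference of 18.0 points (2.02 to 33.0) that excluded 0, but outside the naive-like cluster it was 7.68 points (-10.2 to 25.5). The unthinned KO difference was 10.9 points (-1.90 to 25.2).

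In summed counts, naive and memory genes were lower in KO CD8 T cells as a group. Of 12 measured members 7 were lower and 1 higher, with a median log2 ratio of -0.88 (-1.02 to -0.61, percentile 0.00). Slamf6 was 70.1 CPM in WT and 19.8 in KO (ratio 0.189 to 0.415). S1pr1, which guides egress from tissue, was 75.8 and 25.2, Klf2, a regulator of S1pr1, was 327 and 137, and Il7r was 273 and 141. Lef1, a factor related to TCF1, was 109 and 59.4, and Ccr7 131 and 104 (log2 0.34 with the mean of each cell's CPM). The median was -0.12 with the mean of each cell's CPM, which weighs deep and shallow cells alike, and -0.28 with classes by cluster. It was 0.10 within the naive-like cluster and -1.65 outside it. The residency and chemokine receptor genes had a median of -0.50 (-0.79 to -0.20; percentile 0.04), with 3 of 7 lower and 0 higher. Cxcr3, the receptor of CXCL9 and CXCL10, was 138 CPM in WT and 41.1 in KO (log2 -1.75, ratio 0.226 to 0.390). Itgb7, an integrin chain, was 197 and 72.8, and Cd69, which holds T cells in tissue, was 179 and 107. Counting only genes with at least 200 CPM gave this list a median of 0.10.

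Cytotoxic and effector genes were higher, with 9 of 17 members higher, 2 lower and a median of 0.71 (0.36 to 1.10; percentile 100). Ccl4 was 425 CPM in WT and 1411 in KO (ratio 3.02 to 3.65), Gzmb 607 and 1560 (2.37 to 2.79), Prf1, the pore-forming perforin, 194 and 503 (2.25 to 3.00), and Ifng 98.7 and 238 (1.97 to 2.97). Ccl5 ran the other way, at 6438 and 3746 CPM (log2 -0.78). Gzmc was 8.16 and 438 CPM, but 1 KO cell held 551 of its 885 UMIs, and without each library's top cell its log2 ratio was 5.65. Gzmf was 0.816 and 69.8 CPM with 107 of 141 KO UMIs in 1 cell, and a log2 ratio of 6.42 (ratio 15.1 to 3404) that rests on 1 WT UMI. Without each library's top cell WT was at 0, and the log2 ratio was 2.79 against the floor. A Gzmc UMI was found in 3 WT and 21 KO cells. Within clusters 5, 9 and 11, the KO to WT ratios were 2.03, 3.18 and 2.41 for Gzmb and 2.61, 1.95 and 2.21 for Ccl4. Prf1 (2.09, 0.832 and 1.95) and Ifng (2.23, 0.807 and 1.83) were higher in clusters 5 and 11 but not in cluster 9. The clustering used Gzmb and Prf1, so their levels within clusters were set in part beforehand.

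Inhibitory receptor and exhaustion genes had a median of 0.29, with 1 of 8 higher and 0 lower (percentile 92.7). Havcr2, encoding TIM-3, was 70.1 and 106 CPM (ratio 1.18 to 1.97), Tox, a factor of exhausted T cells, 135 and 195 (1.20 to 1.74), Tigit 264 and 320, and Pdcd1 427 and 491 (1.03 to 1.28). Co-stimulatory receptors had a median of 0.21, with 2 of 8 higher and 0 lower (percentile 77.0). The 2 were Tnfrsf4, encoding OX40, at 115 and 305 CPM (2.21 to 3.21) and Tnfrsf9, encoding 4-1BB, at 321 and 526 (1.46 to 1.84). Tnfrsf18 was 180 and 251 CPM, Icos 75.8 and 56.4. Early response genes of TCR and CD28 signalling had a median of 0.11, with 1 of 5 higher (percentile 45.1). That gene was Il2ra, the high-affinity IL-2 receptor chain, at 17.1 and 67.8 CPM (2.49 to 6.60), which is also in the Treg list (median 0.39, 2 of 6 higher, percentile 97.4; -0.26 with classes by cluster). Gata3 was the only measured member of the CD4 lineage list, with a log2 ratio of -0.51. Th1 genes had a median of -0.01 (percentile 28.1), with Ifng higher and Cxcr3 and Ccl5 lower.

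Cycling genes had a median of 0.64 (0.52 to 0.76; percentile 100), with 9 of 14 higher and 0 lower. Ube2c was 100 CPM in WT and 202 in KO, Ccnb2 53.8 and 115, and Birc5 85.6 and 166. Glycolysis genes had a median of 0.28 with 0 of 9 past 1.5-fold (percentile 98.1), Ldha at 1251 and 1732 CPM and Pgam1 at 283 and 403. Oxidative phosphorylation genes had a median of 0.24 with 1 of 70 higher, Atp5g1 among the largest at 293.6 and 430 CPM (percentile 99.7). Ribosomal protein genes had a median of -0.05 with 1 of 82 higher, Rps27l, and 1 lower, Rps27 (percentile 31.0). Mitochondrially encoded genes had -0.09 with 0 of 13 past 1.5-fold (percentile 10.1). Type I interferon genes had -0.04 with 2 of 9 lower (percentile 19.6), Ifit3 at 119 and 69.3 CPM and Ifit1 at 105 and 68.3, while Ifi27l2a was 1558 and 2270. Ifit1 turned to 0.28 with classes by cluster. MHC class I genes had 0.02 with 0 of 7 past 1.5-fold (percentile 49.4). Stress genes induced by tissue dissociation had -0.50 (-0.66 to -0.39; percentile 0.01), with 3 of 9 lower. These were Fos at 129 and 41.1 CPM, Zfp36 at 177 and 62.4 and Jun at 56.3 and 19.8, and the list median was below 0 in every compared class.

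Transcripts of other cell types were present in the CD8 T cells. Antigen-presenting cell transcripts had a median of -1.94 (-2.41 to -1.63), with 5 of 5 lower. H2-Aa was 170 CPM in WT and 18.3 in KO, and Cd74 611 and 193, but 2 WT cells held 626 of the 749 Cd74 UMIs in WT, and without T cells with over 0.5% of such UMIs the median was 0.45. For the NK cell list only Klre1 was measured, at a log2 ratio of 0.46, and 0 members of the melanoma, B cell and neutrophil lists were.

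The highest and lowest genes in the ranking added to these lists. Among the 10 highest were Serpina3f, a serine protease inhibitor, at 11.4 CPM in WT and 54.5 in KO (2.73 to 9.01), the metallothionein Mt1 at 55.5 and 190 (2.64 to 4.49) and Igfbp7 at 16.3 and 64.4 (2.45 to 6.67). Ccl1, a chemokine, was 12.2 and 139 CPM, with 203 of 281 KO UMIs in 1 cell and a log2 ratio of 2.23 without each library's top cell. Among the 10 lowest were Pydc3, of the interferon-inducible Ifi200 family, at 62.0 and 13.9 CPM (log2 -2.16), and 5830405F06Rik at 640 and 204 (log2 -1.65). The latter is a lincRNA gene at chromosome 6, 41055883 to 41063102, plus strand, whose exons overlap those of the T cell receptor segments Trbv4 and Trbv5.

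**Figure D4:**
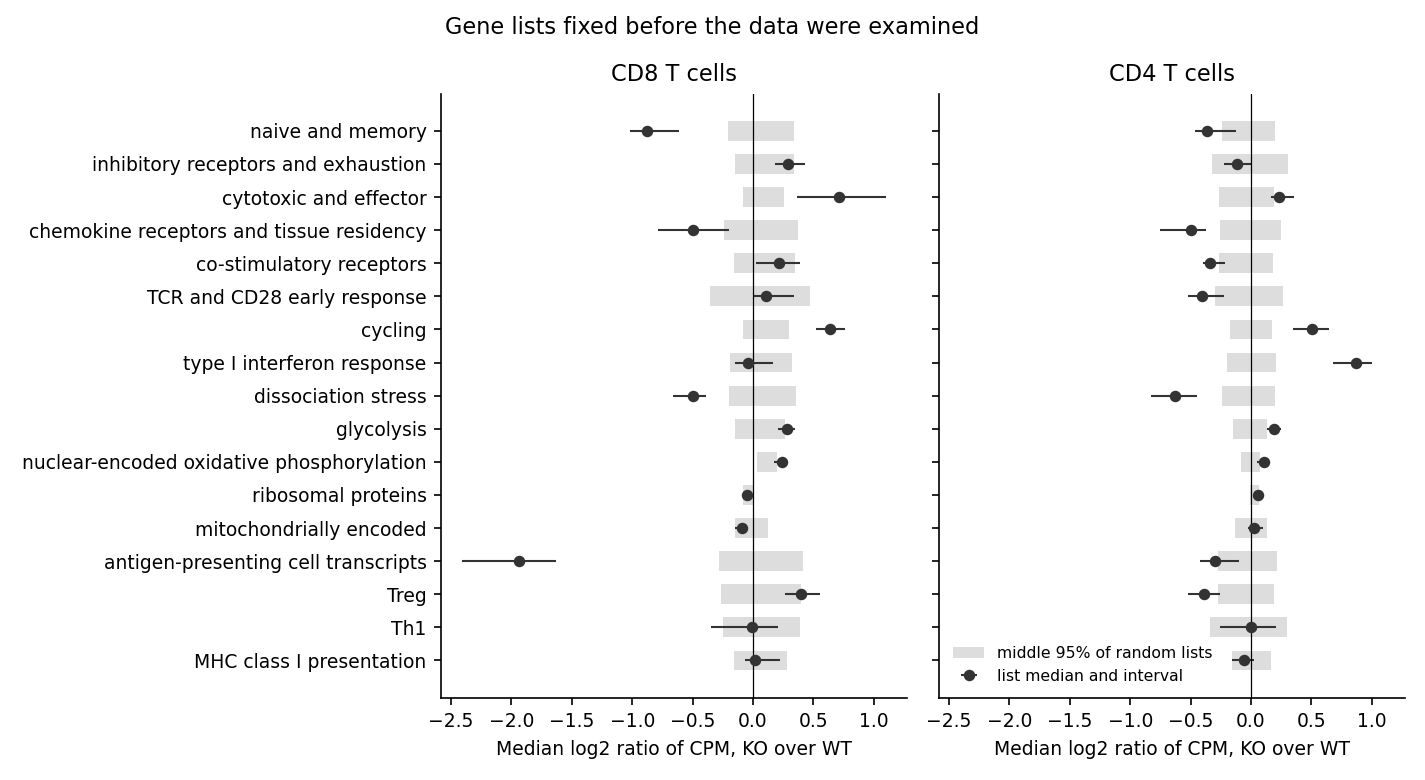
Median log2 ratio of KO to WT CPM for each gene list with at least 3 measured members in both CD8 and CD4 T cells, with 95% intervals from Poisson draws as bars and the middle 95% of random lists in grey. In CD8 T cells the medians were 0.71 for cytotoxic and effector genes and -0.88 for naive and memory genes.

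In the naive-like CD8 cluster (43 WT and 45 KO cells), chosen after the data were seen, Ccr7, Lef1 and Il7r were not lower in KO while Cxcr6 was higher. Ccr7 was 457 CPM in WT and 590 in KO, Lef1 411 and 419, and Il7r 672 and 937 (ratio 1.11 to 1.76). Slamf6 was 145.5 and 77.2 CPM (0.259 to 1.04) and Cd28 85.3 and 77.2. A Cxcr6 UMI was present in 5 of 43 WT cells (11.6%) and 27 of 45 KO cells (60.0%), and after thinning in 2 of 42 (4.76%) and 14 of 43 (32.6%). The naive-like CD4 T cells of the same libraries had it in 0 of 20 and 0 of 34 cells, which allows up to 15% and 8.82%. Outside the naive-like cluster, Il7r was 196 and 62.5 CPM, Slamf6 55.5 and 14.1, Lef1 49.7 and 23.9, Gzmk 242 and 131, Gzmb 724 and 1713, and Cxcr6 414 and 517 (1.11 to 1.40). Gzmk varied by cluster, with ratios of 0.281 to 0.495 in cluster 5, 0.789 to 1.42 in cluster 9 and 2.91 to 44.4 in cluster 11. Outside the naive-like cluster the share with a Cxcr6 UMI after thinning was 35.9% in WT and 62.7% in KO. Averaged over all draws these shares were 43.8% and 64.3%, and in the naive-like cluster 6.37% and 36.7%.

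CD4 T cells of the same libraries show how the libraries differed where the Cre is not described as active. List medians in CD8 and CD4 T cells were -0.50 and -0.50 for residency, 0.64 and 0.51 for cycling, and -0.50 and -0.63 for stress genes. They were -0.88 and -0.37 for naive and memory genes, and 0.71 and 0.23 for cytotoxic genes. By these gates, such differences were thus not confined to CD8 T cells. Clusters 9 and 11, with Cd8b1 and Cd8a among their leading genes, held some of these CD4 T cells. Classes by cluster leave only clusters 2 and 6 as CD4. The CD4 medians of naive and memory and of cycling genes then turned, and that of cytotoxic genes lay near 0. Those of residency and stress genes stayed below 0. By the gates used here, other lists, such as interferon and Treg genes, had medians of opposite sign in CD8 and CD4 T cells. In CD4 T cells, type I interferon genes were higher in KO, and Foxp3 and Ikzf2, factors of regulatory T cells (Tregs), were lower. The cells sat in different clusters in part: cluster 2, led by Cd40lg, held 78 WT and 50 KO CD4 T cells, Treg cluster 6 held 47 and 32, naive-like cluster 1 held 20 and 34, cycling cluster 5 held 15 and 23, cluster 11 held 6 and 16, interferon cluster 14 held 3 and 12, and cluster 9 held 1 and 4. The interferon list had a median of 0.87 (0.68 to 1.01; percentile 100), with 8 of 12 higher and 0 lower. Usp18 was 22.9 CPM in WT and 85.0 in KO, Ifitm3 155 and 342, Rsad2 24.8 and 70.7, and Ifit1 103 and 203. The Treg list had a median of -0.39 with 2 of 7 lower (percentile 0.445), Foxp3 at 197 and 105 CPM (0.428 to 0.665), Ikzf2 at 326 and 187 and Capg at 584 and 406. With classes by cluster the Treg median was 0.25, Ikzf2 0.06 and Capg 0.14. After thinning, 37 of 162 WT CD4 T cells (22.8%) and 24 of 167 KO cells (14.4%) had a Foxp3 UMI, a difference of -8.47 points (-17.2 to 0.352; at 4000 UMIs -22.8, -35.9 to -8.88), and unthinned 58 of 170 and 33 of 171 did, against 5 of 175 and 5 of 186 cDC1s. The median depths were 4065 and 4381 UMIs.

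In CD4 T cells, naive and memory genes had -0.37 with 2 of 11 lower (percentile 0.17), Klf2 at 238 and 145 CPM and Xcl1 at 116 and 54.2 (70 of 122 WT UMIs in 1 cell), and the median was 0.06 with classes by cluster. Residency genes had -0.50 with 3 of 7 lower (percentile 0.02), Cxcr3 at 267 and 138, Itgb7 at 373 and 200 and Rgs1 at 390 and 238. Co-stimulatory receptors had -0.34 with 0 of 8 past 1.5-fold (percentile 0.52), Cd2 at 675 and 504, and 0.25 with classes by cluster. Cytotoxic genes had 0.23 with 5 of 12 higher and 1 lower (percentile 99.1), Klrc1 at 5.72 and 52.7 (4.03 to 26.0), Ifng at 30.5 and 105, and Klrg1 lower at 124 and 38.4. With classes by cluster, the log2 ratio of Klrc1 turned to -0.34 and that of Klrg1 to 0.45, and Ifng turned too. Inhibitory receptors had a median of -0.11 and a mean of 0.03, of opposite sign, with 2 of 6 higher (Tox 73.4 and 132, Lag3 101 and 172) and 1 lower (percentile 24.3), and Pdcd1 at 480 and 345. Early response genes had a median of -0.41 and a mean of 0.13, of opposite sign, with 3 of 8 lower and 1 higher (percentile 0.38). Myc was 88.6 and 39.9 and Nr4a1 129 and 77.5, while Il2 was 15.2 and 208 CPM with 263 of 277 KO UMIs in 1 cell (log2 -0.23 without each library's top cell).

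Cycling genes in CD4 T cells had a median of 0.51 with 6 of 14 higher (percentile 100) and -0.16 with classes by cluster. Stress genes had -0.63 with 5 of 10 lower and 1 higher (percentile 0.00), Fos at 237 and 87.3 CPM, Dusp1 at 535 and 265 and the higher one, Hsp90aa1, at 351 and 708. CD4 lineage genes had -0.28 with 1 of 3 lower, Foxp3. Glycolysis had 0.19 over 10 genes, oxidative phosphorylation 0.11 with 1 of 71 higher, ribosomal proteins 0.06 over 82, mitochondrially encoded 0.03 over 13, MHC class I -0.06 over 7 and Th1 0.00 over 5. Antigen-presenting cell transcripts had -0.30 with 2 of 8 lower and 1 higher. Among the ranked genes, Igfbp7 was 17.2 and 99.3 CPM (log2 -1.11 with classes by cluster), Rln3 73.4 and 18.1, Ramp1 172 and 68.5 and Ddit4, a stress-induced inhibitor of mTORC1, 702 and 339. Chil3 had 1 UMI in WT and 120 in KO, 100 of them in 1 cell. Without each library's top cell WT was at 0 and the log2 ratio 2.40 against the floor. For the melanoma, B cell, neutrophil and NK cell lists 0 members were measured in CD4 T cells. Cxcl9 was at 0 UMIs in WT and 73 in KO, 19.2-fold higher against the floor (lower bound 15.2), but 60 of the 73 were in 1 cell.

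The antigen-presenting cells supply CXCL16 and the CD28 ligands CD80 and CD86. In KO cDC1s the chemokine genes Cxcl9 and Cxcl10, whose products bind CXCR3, were higher, while Cxcl16 was lower and Cd86 was at a like level. Cxcl9 was 93.1 CPM in WT and 334 in KO (3.13 to 4.13; 119 of 260 WT UMIs in 1 cell), and Cxcl10 12.5 and 67.5 (3.75 to 7.93), with 29 of 35 WT and 89 of 211 KO UMIs in 1 cell each and a log2 ratio of 4.18 without each library's top cell. Cxcl16 was 73.8 and 49.6 CPM (0.542 to 0.831), and its exons overlap Zmynd15 on the other strand. Cd80 was 10.0 and 7.67 CPM, Cd86 102 and 98.5, and Cd40 28.7 and 52.8. The ligand list had a median of 0.88 (percentile 100), with 3 of 5 higher, and 0.20 when genes of at least 10 CPM were counted. Interferon genes had 0.24 with 2 of 9 higher (percentile 99.9), Isg15 at 443 and 751 CPM. Stress genes had -0.71 with 7 of 11 lower (percentile 0.00), Jun at 169 and 55.3, Fos at 1292 and 555 and Dusp1 at 628 and 296. MHC class I had 0.11 and class II -0.06, each with 0 of 7 past 1.5-fold. The class joined cluster 0 (139 WT and 126 KO cells) and cycling cluster 10 (36 and 60). Cycling genes had 0.45 with 5 of 13 higher (percentile 100), Ube2c at 48.7 and 122 with 97 of 381 KO UMIs in 1 cell. Glycolysis had 0.05 over 9 genes, oxidative phosphorylation 0.11 over 70, ribosomal proteins -0.04 over 81 and mitochondrially encoded genes -0.03 over 12, with 0 past 1.5-fold in each. Serpina3g was 69.1 and 182 CPM, Il1b, a proinflammatory cytokine, 333 and 80.3, and Nr4a2 74.5 and 20.8. Ifi202b was 59.5 CPM in WT (166 UMIs) and 0 in KO, 62.0-fold lower against the floor (upper bound of the ratio 0.0201).

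Mature DCs had the same direction for Cxcl9, at 29.5 CPM in WT and 408 in KO (8.98 to 22.4). In WT it had 23 UMIs in 3 cells, 19 of them in 1 cell, and in KO 74 of 204 were in 1 cell. The log2 ratio of 5.71 without each library's top cell thus rests on few WT UMIs. Il12b, a cytokine subunit that drives Th1 responses, was 310 and 661 CPM (log2 1.09), Pdcd1lg2, encoding the PD-1 ligand PD-L2, 91.0 and 178, and Ccl22 501 and 795. Cxcl16 was 706 and 749 CPM, Cd80 171 and 178, and Cd86 159 and 208. The ligand list had a median of 0.39 with 5 of 13 higher and 2 lower (percentile 100). Interferon genes had 0.17 with 3 of 13 higher and 1 lower, Isg15 at 891 and 1399 and Ifit3 at 151 and 74.1. Stress genes had -0.41 with 5 of 11 lower (percentile 0.04), Hspa1a at 59 UMIs in WT and 1 in KO and Fos at 142 and 42.0 CPM. MHC class I had 0.18 over 7 genes and class II 0.13 over 6. Glycolysis had -0.02 with 1 of 9 lower, Pgam1, oxidative phosphorylation 0.06 over 69 genes, ribosomal proteins -0.08 over 82 and mitochondrially encoded genes 0.06 over 12. The only measured cycling gene, Hmgb2, was 110 and 50.05 CPM (0.279 to 0.716). Clu was 78.2 and 18.0 CPM and Iigp1 8.97 and 66.1, with 21 of 33 KO UMIs in 1 cell. Fabp4 was 10.3 and 108 CPM, with all 54 KO UMIs in 1 cell.

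KO macrophages had lower Il1b and Tnf transcripts, and their interferon genes had a median above 0, with most members not past 1.5-fold. Il1b was 732 CPM in WT and 168 in KO (log2 -2.13), and Tnf had a ratio of 0.158 to 0.616. The inflammatory list had a median of -0.77 with 1 of 4 higher, Cxcl10 at 94.8 and 247 CPM, and 2 lower, but turned to 0.24 with the mean of each cell's CPM. The tissue macrophage list had 0.49 with 4 of 8 higher and 1 lower, Arg1 at 374 and 618, with 143 of 201 WT UMIs in 1 cell, and Spp1 at 4304 and 954, with 1209 of 2316 WT Spp1 UMIs in 1 cell, and turned to -0.11 under the same alternative. MHC class II genes had -0.38 with 0 of 6 past 1.5-fold (percentile 0.03) and 0.08 under it. Interferon genes had 0.39 with 4 of 13 higher (percentile 99.99), Ifi27l2a at 3736 and 5735, and stress genes -0.82 with 7 of 11 lower (percentile 0.00), Dusp1 at 996 and 404. Ligands had 0.11 with 1 of 6 higher. MHC class I had a median of 0.06 over 7 genes and a mean of opposite sign, -0.00047. Cxcl16 was 184 and 264 CPM (1.10 to 1.87), Cd80 14.9 and 7.38, and Cd86 70.6 and 60.9.

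Among ranked macrophage genes, Mt2 was 5.58 and 95.9 CPM and Mmp12, a macrophage elastase, 162 and 570, with 127 of 309 KO UMIs in 1 cell. Retnla had 0 UMIs in WT and 29 in KO, 24 of them in 1 cell. Ccr7 was 186 and 5.53 CPM with 64 of 100 WT UMIs in 1 cell, and Ccl5 1091 and 129 with 174 of 587 in 1 cell. The T cell marker Cd28 had a UMI in 12 of 63 WT and 1 of 57 KO macrophages. Cxcr6 had 25 and 5 UMIs, and Tcf7 3 and 2. RNA of other cells in this class is thus not separated from a change in macrophages. Ifi202b had 30 UMIs in WT and 0 in KO. Glycolysis genes had a median of 0.25 over 11 genes (percentile 99.6), oxidative phosphorylation 0.11 over 71, ribosomal proteins -0.04 over 82 and mitochondrially encoded genes 0.16 over 12, with 0 past 1.5-fold in each. Cycling genes had 0.04 with 1 of 5 higher, Hmgb2, with 54 of 135 KO UMIs in 1 cell and a log2 ratio of -0.46 with the mean of each cell's CPM. Neutrophil transcripts had -0.12 over 3 genes, carried by few cells: S100a8 was 288 and 485 CPM with 193 of 263 KO UMIs in 1 cell, and S100a9 504 and 465 with 207 of 252. With the mean of each cell's CPM, S100a8 turned to -0.14. The third, G0s2, was 52.0 and 9.22 CPM from 3 WT cells and 1 KO cell. Dct, the only measured melanoma gene, was 22.3 and 70.1 CPM (1.61 to 6.61), with a UMI in 12 of 63 WT and 19 of 57 KO macrophages. In cDC1s and mature DCs 0 members of the melanoma, neutrophil and B cell lists were measured, nor any B cell gene in macrophages.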

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

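Every test of Cxcr6 in naive-like CD8 T cells, the test of the Ifi202b locus and the test of handling were chosen after the result was seen. The other tests of Ifi202b and that of the most stressed cells were set down before theirs. But the explanation by heat-shock differences between WT animals was narrowed after its test, and ratios without top cells were added after. For results set side by side between classes, the difference itself was not tested.

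KO naive-like CD8 T cells carried Cxcr6 more often than WT ones. Depth alone is argued against, since at 2000 UMIs per cell the shares still differed by 27.8 points (10.1 to 44.3). Free RNA is argued against, since 0 of 34 KO naive-like CD4 T cells had Cxcr6, which allows 8.82% at the floor of 3 cells and 10.3% by the Clopper-Pearson bound, below the 44.3 to 74.3% of the CD8 cells. Misplaced effector cells cannot be told apart. Of these cells 3.70% (1 of 27) had a UMI of Gzmb, Pdcd1, Havcr2 or Lag3, against 93.5% (115 of 123) of other KO CD8 T cells with Cxcr6. But the clustering itself used these genes as well as Cxcr6, Prf1 and Tox, so the contrast was set in part beforehand. Prf1 was found in 3 of 43 WT and 9 of 45 KO naive-like cells (ratio 1.06 to 22.5) and Tox in 2 and 8 (0.877 to 42.5). Loss of Tcf7 in the same cells may account for it, as a hypothesis, but cannot be told apart either. KO cells without a Tcf7 UMI differed from those with one by 4.78 points (-25.7 to 33.7), an interval that allows either direction. The split could not decide it at any width, since a Tcf7 UMI may lie outside the deleted part and its absence may follow thinning.

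Ifi202b, at chromosome 1, 173962568 to 173982744, had 335 UMIs in 82 WT barcodes and 0 in KO, and it was the only 1 of 10006 genes seen in at least 30 cells of one library and none of the other. A lack of interferon-responding KO cDC1s is argued against, since the WT share would give 17.4 such KO cells with Ifi202b, where 0 of 51 had it. An interferon state low in heat-shock transcripts is argued against for cDC1s with a UMI of Ifit1, Ifit3 or Rsad2. In such KO cDC1s the Hspa1a ratio was 3.89 (3.17 to 4.79), and 1.02 (0.628 to 1.60) without the top cell on each side. In WT cDC1s split the same way it was 2.32, and 0.764 (0.533 to 1.08) without top cells. No KO cell carried Ifi202b, so a state particular to WT cDC1s with Ifi202b is left open. Their Hspa1a ratio was 0.0801, and Rsad2 was 3.26-fold higher (2.08 to 5.11). Heat-shock differences between WT animals (seen first in these cDC1s, and narrowed to heat shock after its test came out against it) cannot be told apart. In other WT antigen-presenting cells with Ifi202b the Hspa1a ratio was 1.89 (1.31 to 2.69), with Hspa1b at 1.47, Hsph1 at 1.03 and Hsp90aa1 at 1.32. By the rule set down, an interval above 1 counts against this explanation. But 3 of 25 cells carried Hspa1a, and without the top cell on each side its ratio was 0.842 (0.455 to 1.46). The rule set down thus did not allow for the spread between cells, and the question was left open on grounds that were not part of that rule. A sequence or copy difference at the locus between animals may account for it but cannot be told apart either. Of 5 neighbouring family members with at least 50 CPM in cDC1s, Mndal had the largest log2 ratio, 0.33 (0.14 to 0.52). Pydc4, under that limit, was 2.08-fold higher in KO (1.52 to 2.89), and Pydc3 was lower in KO CD8 T cells. Changed neighbours do not decide it, since such a difference could reach them too. In WT cDC1s all 7 Pydc3 UMIs lay in cells with Ifi202b. In other WT antigen-presenting cells the Pydc3 ratio between cells with and without Ifi202b was 16.75 (6.37 to 51.6). But Pydc3 also went with interferon genes: in KO cDC1s all 5 UMIs lay in cells with a UMI of Ifit1, Ifit3 or Rsad2.

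The median of the stress genes was below 0 in all 5 compared classes. A handling difference between the libraries cannot be told apart: the median and its interval lay below 0 in 4 of 4 classes other than CD8 T cells, which restates the pattern. A few very stressed WT cells are argued against, since without the top 10% of cells the cDC1 median was -0.92 (-0.996 to -0.647). Handling and genotype are confounded with 1 library per group, so an effect of the KO on other classes stays open and was not tested.

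Some results pointed in opposite directions in CD8 and CD4 T cells. Co-stimulatory receptors had medians of 0.21 and -0.34, ribosomal proteins -0.046 and 0.061, and the Treg list 0.39 and -0.39. Pdcd1 had log2 ratios of 0.20 and -0.48. With classes by cluster the opposition was lost for co-stimulatory receptors (0.25 in CD4 T cells) and ribosomal proteins (-0.007 and -0.009) and inverted for the Treg list (-0.26 and 0.25). That setting counts the CD4 T cells of naive-like cluster 1 and cycling cluster 5 as CD8. It thus compares other sets of cells and does not decide these directions. These differences were not tested, and the Treg list was measured over different members in each class.

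Signals outside the comparisons were seen as well. Melanoma cells, with Dct, Mlana and Pmel, were 2.04% of WT and 1.20% of KO kept cells although the sort took CD45-positive cells. Cells with markers of both T cells and cDC1s were 2.04% and 0.925%. Among barcodes left out by the filter, 7 of 132 WT (5.30%) and 5 of 133 KO (3.76%) had a UMI of Hbb-bs, a haemoglobin gene of red blood cells.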

How the results depend on the processing

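Alternatives without the naive-like cluster, within it alone, without T cells rich in antigen-presenting cell UMIs, without each gene's top cell and with the mean over all thinning draws were chosen after the data were seen. No paired analysis was possible because the 3 tumors of a group were pooled and carry no pair or barcode, and no library could be left out since there was 1 per group. Counts of kept values cover gene lists, shares and the axis genes first. Of these, 918 values stayed within the counting interval of the value reported, 160 moved out of it and 40 turned, which means a change of sign where the interval reported excluded 0. Where it held 0, the sign changed in 35 of the 918 and in 28 of the 160. For single named genes the numbers were 1366, 183 and 38, with 5 of the 1366 and 6 of the 183 across 0. Keeping doublets moved 0 of 103 values of the first kind, and the mean over all thinning draws 0 of 18. Cd28 in CD8 T cells stayed within its interval in every setting that gave it a value, at -0.14 to -0.03. Cxcr6 stayed above 0, at 0.32 to 2.65, and its share difference at 14.4 to 31.7 points. Tcf7 stayed below 0, at -2.08 to -0.29. The thinning mean was not computed for Cxcr6 by Tcf7. Depth limits scarce transcripts: named genes with 3 or fewer UMIs in both libraries got no value. Below, genes have log2 ratios, lists have medians and shares have KO minus WT points; the 28 are given as crossed 0, and the cause of each change was not tested.

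With the mean of each cell's CPM, Ccr7 turned to 0.34 in CD8 T cells. Oxidative phosphorylation turned to -0.004 in CD4 T cells. S100a8 turned to -0.14, Hmgb2 to -0.46, H2-DMb1 to 0.073 and H2-Eb1 to 0.13 in macrophages. MHC class II turned to 0.085, mitochondrial genes to -0.14, inflammatory genes to 0.24 and tissue macrophage genes to -0.11 in macrophages. Interferon genes crossed 0 to 0.20 in CD8 T cells. Inhibitory receptors crossed 0 to 0.17 and mitochondrial genes to -0.035 in CD4 T cells. Cycling genes crossed 0 to -0.63 in macrophages. Tcf7 moved to -0.79 and Cxcr6 to 0.84 in CD8 T cells. The Th1 list moved to -0.54, antigen-presenting cell transcripts to -0.52, ribosomal proteins to -0.007, stress genes to -0.67, cycling genes to 0.89, inhibitory receptors to 0.52 and naive and memory genes to -0.12 in CD8 T cells. Naive and memory genes moved to -0.078, cytotoxic genes to 0.37, co-stimulatory receptors to -0.15, cycling genes to 0.33, glycolysis to 0.045, ribosomal proteins to 0.078 and the Treg list to -0.20 in CD4 T cells. Mitochondrial genes moved to -0.090, ribosomal proteins to -0.028, glycolysis to 0.15 and interferon genes to 0.48 in cDC1s. Stress genes moved to -0.28 and ribosomal proteins to -0.11 in mature DCs. Neutrophil transcripts moved to -1.75, oxidative phosphorylation to 0.007, interferon genes to 0.58, MHC class I to 0.17 and ligands to 0.80 in macrophages.
With classes by cluster, the CD4 class was clusters 2 and 6 alone, and all other T cell clusters counted as CD8. Ifit1 then turned to 0.28 in CD8 T cells. The Treg list turned to -0.26 and mitochondrial genes to 0.039 in CD8 T cells. Il2 turned to -0.76, Klrc1 to -0.34, Igfbp7 to -1.11, Klrg1 to 0.45, Ltb to 0.099, Ifng to -1.43, Tnfrsf18 to 0.25, Cd28 to 0.079 and Tyms to -0.26 in CD4 T cells. Capg turned to 0.14 and Ikzf2 to 0.057 in CD4 T cells. Naive and memory genes turned to 0.064, co-stimulatory receptors to 0.25, cycling genes to -0.16, glycolysis to -0.14, oxidative phosphorylation to -0.030, ribosomal proteins to -0.009 and the Treg list to 0.25 in CD4 T cells. Interferon genes crossed 0 to 0.17 and early response genes to -0.019 in CD8 T cells. Inhibitory receptors crossed 0 to 0.34, mitochondrial genes to -0.11 and MHC class I to 0.21 in CD4 T cells. Tcf7 moved to -0.88 in CD8 T cells. Naive and memory genes moved to -0.28, cytotoxic genes to 0.30, cycling genes to 0.32, stress genes to -0.84, glycolysis to 0.18, oxidative phosphorylation to 0.14 and ribosomal proteins to -0.007 in CD8 T cells. Share differences of Gzmb moved to 10.7 points, Slamf6 to -4.35 and Cxcr6 to 14.4 in CD8 T cells. Cytotoxic genes moved to 0.003, residency genes to -0.25 and stress genes to -0.32 in CD4 T cells.
With gates that ignored the other co-receptor, the Treg list turned to -0.093 and mitochondrial genes to 0.009 in CD8 T cells. Glycolysis moved to 0.093, ribosomal proteins to -0.030 and antigen-presenting cell transcripts to -2.53 in CD8 T cells. Antigen-presenting cell transcripts moved to -1.14, mitochondrial genes to 0.12, glycolysis to 0.13 and interferon genes to 0.67 in CD4 T cells.
Without cells with a UMI of Mki67 or Top2a, Dusp2 turned to 0.064, H2-Aa to 1.39 and Cd74 to 0.077 in CD8 T cells. Antigen-presenting cell transcripts turned to 0.42 in CD8 T cells. Tcf7 moved to -1.03 and Cxcr6 to 1.14 in CD8 T cells. Mitochondrial genes moved to -0.057, ribosomal proteins to -0.031, oxidative phosphorylation to 0.17, cycling genes to 1.27, early response genes to 0.73, inhibitory receptors to 0.66 and naive and memory genes to -0.35 in CD8 T cells.
Counting genes of at least 200 CPM, which leaves fewer members, residency genes turned to 0.10 in CD8 T cells. Tissue macrophage genes turned to -0.38 and inflammatory genes to 0.084 in macrophages. Early response genes crossed 0 to -0.053, interferon genes to 0.42 and the Th1 list to 0.24 in CD8 T cells. The Th1 list crossed 0 to -0.40 in CD4 T cells. Interferon genes crossed 0 to -0.11 in mature DCs. Neutrophil transcripts crossed 0 to 0.32 in macrophages. Cytotoxic genes moved to 0.26, co-stimulatory receptors to 0.59, stress genes to -0.28 and antigen-presenting cell transcripts to -1.60 in CD8 T cells. Interferon genes moved to 0.60, cycling genes to 0.27, residency genes to -0.90, cytotoxic genes to 0.16 and inhibitory receptors to -0.27 in CD4 T cells. Ligands moved to 1.84 in cDC1s. Stress genes moved to -0.34 in mature DCs. Ligands moved to 0.52 and cycling genes to 0.61 in macrophages.
Counting genes of at least 10 CPM, antigen-presenting cell transcripts turned to 0.18 in CD4 T cells. Inflammatory genes turned to 0.54 in macrophages. Early response genes moved to -0.17 and cytotoxic genes to 0.37 in CD4 T cells. Ligands moved to 0.20 and interferon genes to 0.47 in cDC1s. Neutrophil transcripts moved to -1.45 in macrophages.
With no added cell filter, the share difference of Gzmk crossed 0 to -7.44 points in CD8 T cells. Mitochondrial genes moved to -0.033 in CD8 T cells. Antigen-presenting cell transcripts moved to -1.68 in CD4 T cells. Mitochondrial genes moved to 0.16 and MHC class II to 0.22 in mature DCs.
At a minimum of 1000 UMIs per cell, cytotoxic genes moved to 0.11 in CD4 T cells. Ribosomal proteins moved to -0.066 in macrophages.
At Leiden resolution 2, ribosomal proteins turned to 0.001 in macrophages. Neutrophil transcripts crossed 0 to 0.22 in macrophages. Stress genes moved to -0.61 and tissue macrophage genes to 0.15 in macrophages.
With TMM scaling, ribosomal proteins turned to 0.029 in macrophages. Inhibitory receptors crossed 0 to 0.083 in CD4 T cells. Ribosomal proteins moved to 0.10 and oxidative phosphorylation to 0.15 in CD4 T cells. Ribosomal proteins moved to -0.053 in cDC1s. Mitochondrial genes moved to 0.22, oxidative phosphorylation to 0.17 and glycolysis to 0.31 in macrophages.
With CPM over the remaining genes once ribosomal, mitochondrial and antigen receptor genes were out, ribosomal proteins moved to -0.085 in CD8 T cells, 0.079 in CD4 T cells and -0.054 in cDC1s. Neutrophil transcripts moved to -1.31 in macrophages.
Thinned to 4000 UMIs, share differences of Tcf7 moved to -26.3 points, Pdcd1 to 23.4, Havcr2 to 12.8 and Tox to 23.6 in CD8 T cells. The share difference of Foxp3 moved to -22.8 points in CD4 T cells.
Without thinning, share differences of Havcr2 moved to 19.2 points, Lag3 to 17.4, Tox to 26.9, Ifng to 18.1, Cx3cr1 to 10.2 and Mki67 to 16.8 in CD8 T cells.
Without the naive-like cluster, the share difference of Cxcr6, without minus with Tcf7, crossed 0 to -5.85 points in WT CD8 T cells. Tcf7 moved to -2.08 in CD8 T cells. Ribosomal proteins moved to -0.010, stress genes to -0.28, inhibitory receptors to 0.18 and naive and memory genes to -1.65 in CD8 T cells. Share differences of Il7r moved to -26.2 points and Gzmb to 35.6 in CD8 T cells. Naive and memory genes moved to -0.45 in CD4 T cells.
Within the naive-like cluster alone, S1pr1 turned to 0.094, Pdcd1 to -0.28 (set by the floor, with 4 UMIs in 1 WT cell and 0 in KO), Il7r to 0.48, Ccr7 to 0.37, Lef1 to 0.026, Tigit to -1.45, Ifit3 to 0.97 and Ifit1 to 0.55 in CD8 T cells. Mitochondrial genes turned to 0.049, ribosomal proteins to 0.008, glycolysis to -0.38, cycling genes to -0.28 and naive and memory genes to 0.10 in CD8 T cells. The share difference of Pdcd1 turned to -2.38 points in CD8 T cells. Hsp90aa1 turned to -0.11, Cd2 to 0.071, Rgs1 to 0.64, Ltb to 0.010 and Ddit4 to 1.75 in CD4 T cells. Cytotoxic genes turned to -1.06, residency genes to 0.17, co-stimulatory receptors to 0.071, early response genes to 0.018, glycolysis to -0.068, oxidative phosphorylation to -0.066, ribosomal proteins to -0.069 and the Treg list to 1.02 in CD4 T cells. Interferon genes crossed 0 to 0.61 and early response genes to -0.58 in CD8 T cells. Share differences of Il7r crossed 0 to 10.0 points and Lag3 to -4.76 in CD8 T cells. MHC class I crossed 0 to 0.11, mitochondrial genes to -0.059, CD4 lineage genes to 0.39 and inhibitory receptors to 2.23 in CD4 T cells. The share difference of Foxp3 crossed 0 to 3.03 points in CD4 T cells. Cxcr6 moved to 2.65 and Tcf7 to -0.29 in CD8 T cells. Cytotoxic genes moved to 0.27, stress genes to -0.99, oxidative phosphorylation to 0.016, antigen-presenting cell transcripts to -0.11, the Treg list to 1.14 and the Th1 list to -0.94 in CD8 T cells. Share differences of Mki67 moved to 0 points, Gzmb to 2.33, Ccr7 to 24.6 and Tcf7 to -1.11 in CD8 T cells. Naive and memory genes moved to -0.034, cycling genes to 0.17, interferon genes to 1.16, stress genes to -1.12, antigen-presenting cell transcripts to -0.55 and the Th1 list to 1.34 in CD4 T cells.
Without T cells with over 0.5% antigen-presenting cell UMIs, Cd74 turned to 0.56, H2-Ab1 to 0.72 and H2-Aa to 1.54 in CD8 T cells. Antigen-presenting cell transcripts turned to 0.45 in CD8 T cells. The share difference of Mki67 turned to -0.257 points in CD8 T cells, where 2 WT and 1 KO cells were left out and a new thinning draw was made. Early response genes moved to -0.56 and cycling genes to 0.65 in CD4 T cells.
Without each gene's top cell per library, Il2 turned to -0.23 in CD4 T cells. S100a8 turned to -0.27 in macrophages.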

Other observations

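No test was run for this part, and its genes were chosen after their values were seen.

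Values in cDC2s and monocytes are given here although these classes were too few for a comparison (45 and 30 WT cells). Cxcl9 in cDC2s was 243 CPM in WT and 729 in KO (ratio 2.56 to 3.54; 66 of 176 WT UMIs in 1 cell), and in monocytes 122 and 559. Serpina3g had ratios of 2.64 in cDC1s, 3.91 in cDC2s, 2.98 in mature DCs (30 of 61 KO UMIs in 1 cell), 1.70 in macrophages (34 of 72 in 1 cell) and 1.20 in monocytes (0.787 to 1.88). Gbp2, a guanylate-binding protein of cell-autonomous defence, was 2.50-fold higher in cDC1s, 2.38-fold in cDC2s and 1.24-fold in monocytes, and Iigp1, a related GTPase, 2.46-fold, 2.44-fold and 2.74-fold. Cxcl10 in monocytes was 1026 and 2260 CPM. Macrophages had Cxcl9 at 301 and 319 CPM, with 99 of 162 WT UMIs in 1 cell, and Iigp1 at 40.9 and 111, with 32 of 60 KO UMIs in 1 cell.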
